A study of Mus musculus with 6 samples.

How the data were processed

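The series held 6 bulk RNA-seq libraries from the left side of the brain of male mice, 3 wild type and 3 homozygous for the Top2b-low allele. Groups and replicate numbers came from the sample titles. Per the labels' protocols, total RNA was taken up with a column kit, polyadenylated RNA was selected with oligo-dT beads, stranded libraries were built and they were circularised with an MGI conversion kit. Per the labels, tissue was taken at 10 weeks, while the series text gives 3.5 months. The series text counts the mice per genotype, so replicates were taken as separate animals.

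The authors deposited 1 table of normalised counts, a signal per gene and library, with 78298 Ensembl mouse gene identifiers. Per the submitters' processing notes, RSEM and the mm39 build were used. The version of RSEM, the aligner and the annotation are not given in the sources used here, nor whether counting used strand. In each library every deposited value was a whole multiple of its smallest value above 0 (100% of values, tolerance 1e-06 reads). The whole-number counts behind them could thus be recovered and are called reads below. Whether they were counts of reads or rounded RSEM estimates is not given. The factors that the authors had divided by ran from 0.798 to 1.69 and equalled the median-ratio size factors recomputed with DESeq2 from those reads. Library totals ran from 16963067 to 35246703 reads, and 25468 to 30367 genes were above 0. A count of 3 reads equals 1.77 to 3.76 normalised counts, depending on the library. Gene symbols came from a table of identifiers and symbols for GENCODE vM21, which matched 51498 identifiers and 99.4% or more of the reads in each library. That annotation is of GRCm38 and the table of mm39, so it served only for symbols, chromosomes, span classes and transcript GC content, and no coordinates are given.

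Expression was compared on log2(normalised count + 1), the pseudocount being 1, for the 17391 genes with a mean of at least 10 over the 6 libraries. Fold changes on this scale understate the change of low genes. Genotypes were compared with limma 3.58.1 (empirical Bayes with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. No covariate entered this model. Fixed gene lists with at least 5 tested members, 41 of 42, were tested with camera at a preset correlation of 0.01, adjusted over the 41 lists, with an estimated correlation and fry beside it. The sex check list had fewer tested members and is given as values. Gene length was examined as the mean log2 level of genes spanning over 100 kb minus that of the others in each library (16515 genes with a span), with an exact permutation test over the 20 assignments of 3 labels to 6 libraries. Calls per chromosome were compared with Fisher's exact test. As alternatives, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered reads. Lists, tests, the main design and most alternatives were fixed before the data were examined.

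The genes named were Top2b, then genes past the threshold by size of change. None passed, so the rule took the 6 highest and 6 lowest by unadjusted p among genes with non-overlapping groups, a mean above the median of the tested genes and an official symbol. It also took up to 4 members of each list described, by smallest unadjusted p. Genes outside the rule are given as chosen after their values were seen.

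The titles give both genotypes replicate numbers 1 to 3, so the pairing was checked. The correlation of the deviations from the group means between libraries of the same number was 0.33, 0.35 and 0.68. This was above 0.1 for each pair, and by the rule set beforehand the numbers were taken to pair the samples. The pairing comes only from these values, and mainly from the pair of libraries named N22. Wild type replicate 1 also correlated with Top2b-low replicate 2 (0.37), and wild type replicate 2 with Top2b-low replicate 1 (0.24). The rule thus passes for either matching of replicates 1 and 2, and the values do not tell which is right. Within groups no 2 libraries agreed within sampling noise, the chi-square per degree of freedom of their counts being 4.16 to 39.3.

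Settings added after seeing the data were a term for the N22 libraries, the 4 libraries outside N22, the N22 pair, the replicate block with edgeR and DESeq2, the omission of single replicates for the imprinted genes, and the length difference within pairs and with an estimated correlation. Correlations of deviations from the genotype means were tested by rearranging libraries within genotypes only. The fits were tested on simulated counts for the 17391 genes of the comparison of Top2b-low with wild type. There were 5 runs, with 200 genes changed in each and the real dispersions and N22 difference. The changed genes were drawn from the 13689 with a mean of at least 50, so the shares recovered do not cover lower genes. Limma without the N22 term recovered 17.0% of genes changed 1.5-fold, 64.5% of those changed 2-fold and 94.2% of those changed 4-fold, with 0.4 false calls per run. DESeq2 with the N22 term recovered 74.0%, 94.9% and 99.7%, with 14.6 false calls per run, limma with that term 76.4%, 95.5% and 99.7%, with 14 false calls, and edgeR with it 78.2%, 95.8% and 99.7%, with 21.4. A list shifted by a known amount was called by camera in 5 of 5 runs and an unshifted list in 0. The simulated genes varied independently, and the shift was larger than the mean change of most lists called below. These runs thus cannot show how camera with the preset correlation does on lists whose genes vary together, such as ribosomal genes (estimated correlation 0.85).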

Results

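Polyadenylated RNA from the left side of the brain was sequenced in 3 wild-type and 3 Top2b-low male mice, 1 library per mouse. Top2b encodes topoisomerase IIβ, the type II DNA topoisomerase of postmitotic neurons. Top2b-low mice were homozygous for an allele in which CRISPR/Cas9 had placed an auxin-inducible degron, a peptide tag that marks a protein for degradation in the presence of auxin, at the start of the Top2b coding sequence. Per the labels, no compound was given. All 3 Top2b-low libraries carry the same genotype label, by which they were grouped, but the library name of replicate 3 ends in dNdN where the other names end in Homo. The labels do not say what dNdN means, so whether replicate 3 carries the same allele is not settled here. The labels state 2 ages for the mice, 10 weeks and 3.5 months, and do not resolve which applies. The comparison asked how lowered Top2b expression alters the transcriptome of the adult brain. The deposited table gave normalised read counts, from which whole-number counts, called reads here, could be recovered. They came to 17348164, 16963067 and 28629911 reads in wild type replicates 1 to 3 and to 17237421, 17413959 and 35246703 in Top2b-low replicates 1 to 3. Transcripts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in all 6 libraries, Ddx3y at 1284 to 1747 normalised counts.

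Top2b (ENSMUSG00000017485, chromosome 14) was lower in each Top2b-low library than in each wild-type library. Its normalised count was 3160, 3014 and 2485 in wild type replicates 1 to 3 and 2152, 2314 and 1965 in Top2b-low replicates 1 to 3. The group means were 2886 ± 355 and 2144 ± 175 (SD, n = 3 each), a level 25.7% lower in Top2b-low mice. The log2 fold change was −0.42 with an SE of 0.11, and its 95% interval ran from 10.6% to 37.9% lower. This difference did not pass limma's test over all genes (unadjusted p = 0.00629, Benjamini-Hochberg adjusted p = 0.99997). The two-sided exact permutation test on the 6 values gave p = 0.1, the smallest that 3 against 3 allows. With a term for the replicate number, limma gave an adjusted p of 0.395, edgeR 0.260 and DESeq2 0.000783. The term cannot change limma's fold change, since each number holds 1 library of each genotype. The edgeR and DESeq2 fits with it were added after the data were examined.

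**Figure D1:**
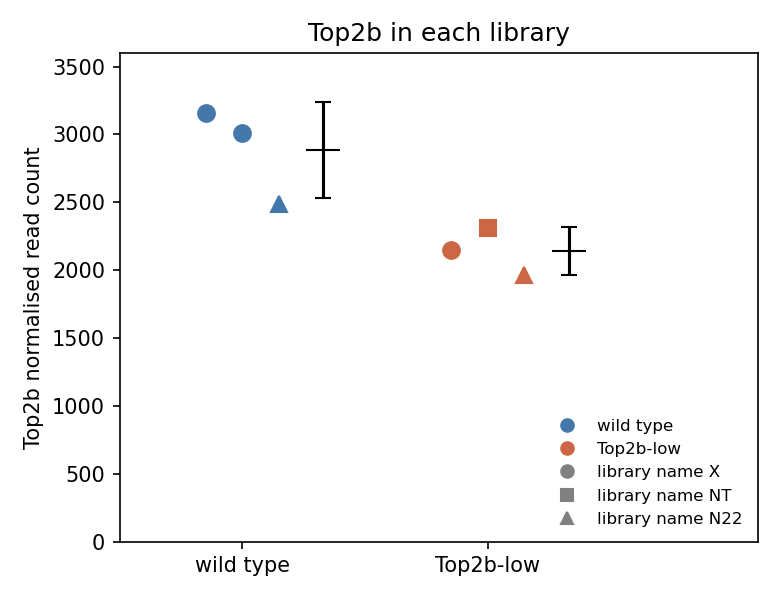
Normalised read count of Top2b (vertical axis, from 0) in each of the 6 libraries, with the mean and SD of each group (n = 3) beside the points and the start of the library name shown by the symbol. The Top2b-low libraries lie between 1965 and 2314 and the wild-type libraries between 2485 and 3160.

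Most markers of the cerebellum were lower in 2 of the libraries, 1 of each genotype. Wild type replicate 3 and Top2b-low replicate 3 have library names that begin with N22, while the other 4 names begin with X or NT. Gabra6, a GABA receptor subunit of cerebellar granule cells, averaged 2119 normalised counts in the other 4 libraries and 0.65 in the N22 libraries. Cbln3, secreted by granule cells, averaged 5753 and 13.6, the granule cell cadherin Fat2 3124 and 4.98, and the Purkinje cell gene Pcp2 882.0 and 9.0. These 4 genes were chosen after their values were seen. The 24 cerebellar markers were on average 3.58 log2 units lower in the N22 libraries, with an SD over genes of 2.77, and the 12 serotonergic and noradrenergic markers, genes of brainstem nuclei, were 1.36 lower. With genotype in the model, limma found 1963 genes higher and 2901 lower in the N22 libraries at an adjusted p under 0.05, of 17391 tested. The first principal component held 54.6% of the variance and placed the N22 libraries at 43.8 and 54.5 and the other 4 between −29.1 and −21.0. Each genotype held 1 N22 library, so genotype was also compared with an N22 term and among the other 4 libraries, settings chosen after the data had been examined. In those 4 libraries Top2b was 27.7% lower in the Top2b-low mice, and in the N22 pair, which has no replicate, it was 20.9% lower.

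**Figure D2:**
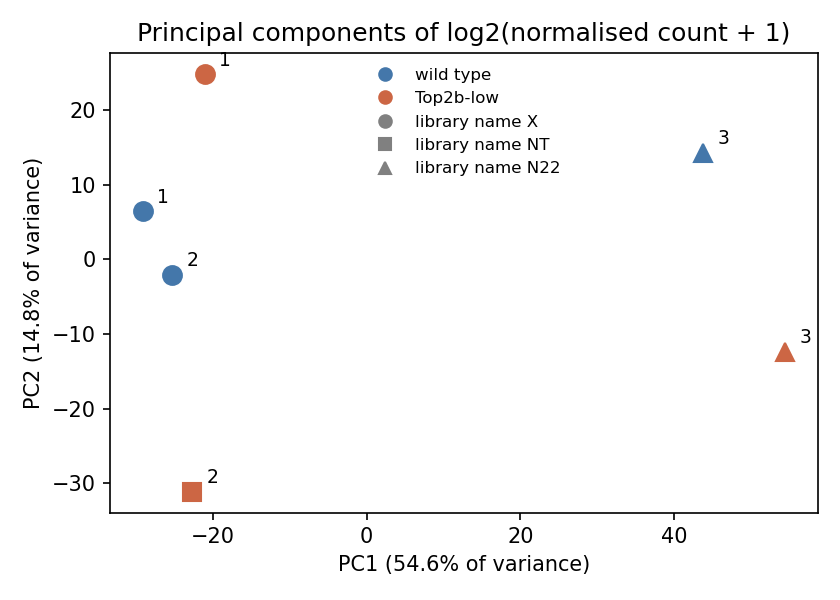
Scores of the 6 libraries on the first and second principal components (unitless) of log2(normalised count + 1) over the 17391 tested genes, labelled with the replicate number. Replicate 3 of each genotype lies at 43.8 or above on the first component and the other 4 libraries at −21.0 or below.

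No gene passed the test between genotypes, in either direction. Among the genes with the smallest unadjusted p and non-overlapping groups, the kinase Camkk2 averaged 4889 ± 202 normalised counts in wild type and 5683 ± 232 in Top2b-low mice (SD, n = 3 each), 16.2% higher. Kdm6a, an X-linked histone demethylase, was 18.6% higher, the semaphorin receptor Plxnd1 18.0%, the synaptic scaffold Cnksr2 17.6% and Ipcef1 14.5%. Npas4, a transcription factor induced by neuronal activity, averaged 275 ± 80.4 and 492 ± 182, and its highest value, 700.5, was in Top2b-low replicate 3. On the lower side stood Zcchc12 (2193 ± 272 against 1488 ± 283), the tubulin-binding Tppp3 (879 ± 49.4 against 646 ± 71.6), the galactosyltransferase B3galt5 (1534 ± 162 against 1185 ± 52.8) and the prostaglandin D synthase Ptgds (11946 ± 509 against 10016 ± 491, 16.2% lower). Srp54b, a subunit of the signal recognition particle which has near-identical copies in the mouse genome, averaged 1603 ± 246 and 1159 ± 47.6. All of these genes had a limma adjusted p of 0.99997 and none passed that test. At an unadjusted p under 0.05 limma left 262 genes, 89 higher and 173 lower, where libraries without further structure give 869.6 by chance. The N22 split is such a structure, and with the N22 term or the replicate block limma left 1011 and 1169. Over all 6 libraries without further terms, edgeR's quasi-likelihood test and DESeq2 on the recovered reads also called 0 genes, with 250 and 191 at an unadjusted p under 0.05. The groups did not overlap for 998 genes, 5.74% of those tested, where chance gives 10% in libraries without such structure.

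Terms for the N22 libraries or for the replicate number brought calls from DESeq2 and none from limma or edgeR. With the N22 term DESeq2 called 1 gene higher and 20 lower, and with the replicate block 2 higher and 12 lower, with 12 genes shared. The genes of this paragraph other than Top2b were chosen after their values were seen. With the N22 term Camk2a, the calcium/calmodulin kinase of forebrain excitatory neurons, rose by 0.29 on the log2 scale (SE 0.06, adjusted p = 0.0019). Top2b fell by 0.42 (SE 0.07, adjusted p = 2.69e-05). Agt, the angiotensinogen made by brain astrocytes, fell by 0.75 (SE 0.12, adjusted p = 1.89e-05) and Slc6a5, the glycine transporter of hindbrain inhibitory neurons, by 0.99 (SE 0.17, adjusted p = 2.08e-05). Slc6a5 counted 855, 1018 and 42.0 in wild type replicates 1 to 3 and 587, 422 and 14.8 in Top2b-low replicates 1 to 3, so its level also followed the N22 split. Spp1, Dgkk, Igsf1, Zim1, Ngb, Ret, Gal and the hypothalamic transcription factor Nkx2-1 were among the others lower, as were Ptgds, Tppp3, B3galt5 and Srp54b. The N22 term does not model other differences in tissue content, such as those of hindbrain and hypothalamic genes described below. Whether these calls follow them was not tested. Among the 4 libraries outside N22, DESeq2 called 5 genes, all lower: Zbtb16, Slc6a5, Top2b, Spp1 and the unnamed ENSMUSG00000140331, where limma called 0 (818 at an unadjusted p under 0.05). Over the alternatives run, the adjusted p of Top2b ranged from 2.69e-05 to 1, with 0.224 the lowest from limma and 0.225 from edgeR.

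Of 41 gene lists tested with limma's camera, 22 stood apart from the other genes with a preset correlation of 0.01 at an adjusted p under 0.05, 9 higher and 13 lower in Top2b-low mice. With an estimated correlation 0 lists did, with adjusted p from 0.475 to 0.816 among those 22, and fry, which tests whether a list's genes move 1 way on balance, called 0. No member of any list passed limma's test over all genes or adjusted over the list alone. For 2 lists, glutamatergic neurons and oligodendrocyte precursors, the list means of the 3 wild-type and 3 Top2b-low libraries did not overlap. Chance gives 4.1 where libraries are neither paired nor split as by N22, so this count cannot be read as fewer than chance. With the replicate block 20 lists were called. With the N22 term 20 were called too, and in the 4 libraries outside N22 16 of the 22 were called in the same direction, and the GABAergic, pituitary, astrocyte, oligodendrocyte precursor, ependymal and mitochondrially encoded lists were not. Array weights ended the calls of those 6 lists and of the interferon list. With the start of the library name as a term the channel, presynaptic, GABAergic, ependymal, interferon, protocadherin and ribosomal lists were no longer called and the nuclear respiratory list was called higher (0.07, adjusted p = 0.00098), and with edgeR or DESeq2 the GABAergic and nuclear respiratory lists were not. Calls also ended with no filter (channels, GABAergic, ependymal, mitochondrially encoded, protocadherins), with quantile normalization (presynaptic, mitochondrially encoded), with a mean of at least 50 (GABAergic) and without limma's trend (GABAergic, astrocyte, nuclear respiratory). Without wild type replicate 3, which leaves the N22 library of the other genotype without a counterpart, the count was 13. Without Top2b-low replicate 3, which does the same for wild type, it was 16. The N22 difference then enters the genotype difference. List means given below without either replicate 3 thus mix the 2 and do not by themselves show an unstable genotype difference. An exact permutation test on the library means of a list cannot go below p = 0.1 with 3 against 3.

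Hypothalamic neuropeptide genes had 12 of 16 members lower and a mean log2 fold change of −1.34 (median −0.55). The mean was −0.67 with array weights, −0.86 with DESeq2, −0.89 with edgeR, and −0.81 with limma and −0.45 with DESeq2 in the 4 libraries outside N22, and the list was called under each of these with the preset correlation but not in all 6 libraries with an estimated correlation (adjusted p = 0.475). The list mean, as a deviation from the 6-library average, was 0.67 ± 0.36 in wild type and −0.67 ± 0.98 in Top2b-low mice (SD, n = 3 each), and the low level lay in replicates 2 and 3. Gal (galanin) counted 69.2, 45.1 and 88.2 in wild type and 34.5, 12.1 and 8.87 in Top2b-low mice. Avp, the vasopressin gene, counted 182, 167 and 282 against 148, 3.64 and 4.73, and Trh (thyrotropin-releasing hormone) 165, 174 and 255 against 149, 25.5 and 46.7. Adcyap1, which encodes the peptide PACAP, averaged 461 ± 24.0 and 371 ± 6.31. Of the 16 members 8 had an unadjusted p under 0.05. The camera adjusted p was 5.36e-09 with the preset correlation. Without Top2b-low replicate 1, Avp alone passed limma's test over all genes (log2 fold change −5.32, adjusted p = 0.0227).

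**Figure D3:**
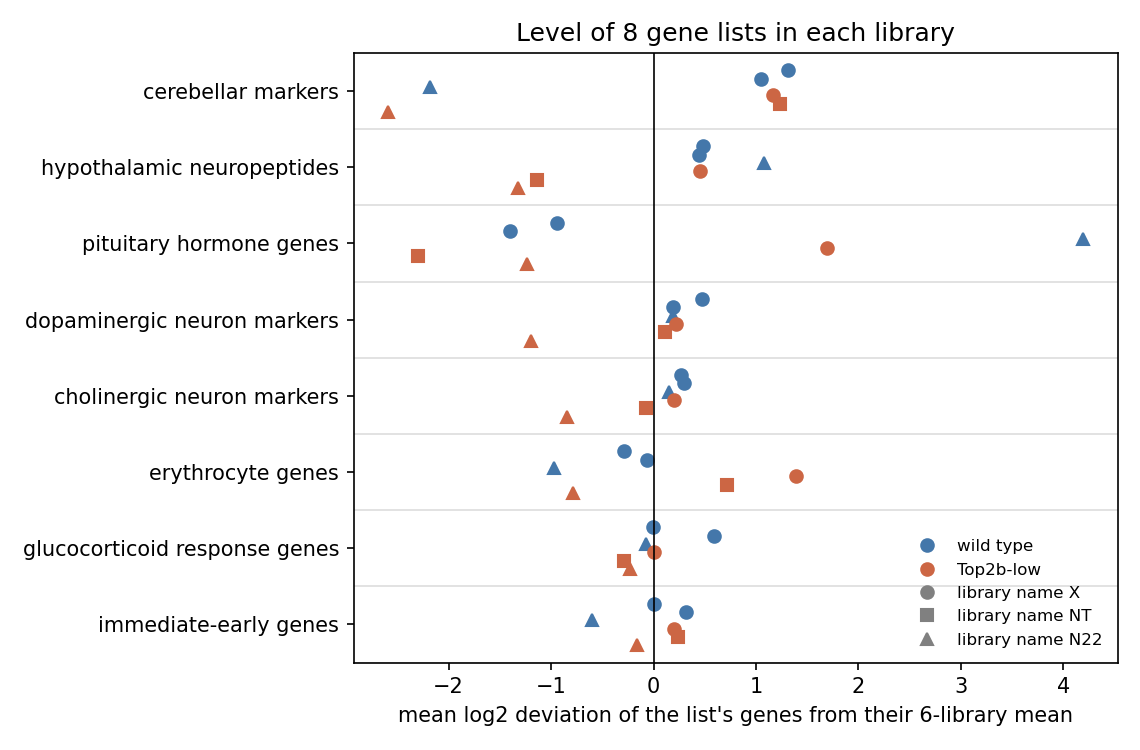
Mean log2 deviation of each list's genes from their 6-library mean (horizontal axis) for 8 gene lists, 1 point per library, coloured by genotype and with the symbol giving the start of the library name. Cerebellar markers lie at −2.18 and −2.59 in the N22 libraries, and hypothalamic neuropeptides at −1.14 and −1.33 in Top2b-low replicates 2 and 3.

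Cholinergic and dopaminergic neuron markers were lower on balance, mostly in Top2b-low replicate 3. All 12 cholinergic markers were lower, with a mean log2 fold change of −0.48 and list means of 0.24 ± 0.08 and −0.24 ± 0.54 (SD, n = 3 each). The basal forebrain transcription factor Lhx8 averaged 48.8 ± 1.11 normalised counts in wild type and 23.3 ± 8.60 in Top2b-low mice, and Ecel1 494 ± 103 and 275 ± 97.8. Gbx1 and Prph were lower too, with log2 fold changes of −0.87 and −0.57. Of 15 dopaminergic markers 12 were lower, with a mean of −0.58. The dopamine transporter Slc6a3 counted 265, 238 and 341 in wild type and 230, 194 and 26.0 in Top2b-low mice, and the synthesis enzyme Ddc 431, 256 and 413 against 273, 262 and 175. Sncg and Ret, the GDNF family receptor, had log2 fold changes of −0.53 and −0.73. The camera adjusted p was 1.13e-07 for the cholinergic and 1.93e-05 for the dopaminergic list, and the adjusted p = 0.480 with an estimated correlation for both. Without Top2b-low replicate 3 the means were −0.18 and −0.12, and the dopaminergic list was no longer called. In the 4 libraries outside N22 they were −0.23 and −0.17, and with array weights −0.26 and −0.35.

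Glucocorticoid response genes and chaperones were lower, with the highest levels in wild type replicate 2. Of 20 glucocorticoid response genes 18 were lower, with a mean of −0.34 and list means of 0.17 ± 0.36 and −0.17 ± 0.15 (SD, n = 3 each). The kinase gene Sgk1 counted 2620, 3861 and 2490 in wild type and 2361, 1788 and 1392 in Top2b-low mice. Map3k6, Arrdc2 and the NF-κB inhibitor Nfkbia had log2 fold changes of −0.65, −0.53 and −0.40. Of 21 heat shock and chaperone genes 20 were lower, with a mean of −0.15, among them Cryab (−0.23), Sdf2l1 (−0.30), Hspb1 (−0.49) and Manf (−0.21). Camera gave adjusted p of 1.13e-07 and 4.62e-05, and the adjusted p = 0.475 and 0.480 with an estimated correlation. Without wild type replicate 2 the means were −0.13 and −0.02 and the chaperone list was no longer called, while without wild type replicate 3 the chaperone mean was −0.29 and without Top2b-low replicate 3 it was −0.09. With array weights the glucocorticoid mean was −0.22. The chaperone mean was −0.22 in the 4 libraries outside N22, and −0.23 there with DESeq2, against −0.0075 in the N22 pair.

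Markers of forebrain excitatory and striatal neurons and immediate-early genes were higher on balance, by small amounts. Of 20 glutamatergic neuron markers 16 were higher, with a mean of 0.12 and list means of −0.06 ± 0.01 and 0.06 ± 0.06 (SD, n = 3 each). Camk2a averaged 41189.5 ± 7092 and 50067 ± 6871, and the vesicular glutamate transporter Slc17a7 and the transcription factor Neurod2 had log2 fold changes of 0.21 and 0.23. Slc17a6, the transporter of thalamic and brainstem neurons, went the other way (−0.32). Of 22 striatal markers 16 were higher, with a mean of 0.08, among them the dopamine receptor Drd1 (0.19), Foxp1 (0.18) and the enkephalin gene Penk (0.18). Of 33 immediate-early genes 26 were higher, with a mean of 0.19, including Npas4 (0.82), Btg2 (0.57) and Junb (0.38), while Scg2 was lower (−0.27). The camera adjusted p was 0.00086, 4.62e-05 and 0.00027, and the adjusted p = 0.475, 0.480 and 0.545 with an estimated correlation. The glutamatergic mean was 0.09 and the striatal mean 0.02 without Top2b-low replicate 3, and both calls ended. Without the wild-type replicates 1, 2 and 3 and Top2b-low replicate 2 in turn the striatal mean was 0.04, 0.03, 0.17 and 0.15. The immediate-early mean turned to −0.07 without wild type replicate 3, and it was 0.39, 0.11 and 0.31 without wild type replicate 2, Top2b-low replicate 2 and Top2b-low replicate 3. The immediate-early mean was 0.06 in the 4 libraries outside N22, against 0.44 in the N22 pair. Immediate-early genes stood at −0.57 in N22 minus the other libraries, a difference that enters the means without either replicate 3.

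Presynaptic vesicle genes, voltage-gated channels and clustered protocadherins were higher on balance by under 5%. Of 30 presynaptic genes 22 were higher, with a mean of 0.06, among them Rims1 (0.20), the complexins Cplx2 (0.18) and Cplx3 (0.47), and Erc2 (0.18). Of 46 voltage-gated sodium, calcium and potassium channel genes 33 were higher, with a mean of 0.04, and the potassium channel genes Kcnh1 (0.15) and Kcnq5 (0.23) stood with Kcnn3 on the lower side (−0.23). Of 57 clustered protocadherins, cell surface recognition proteins read from promoters of 3 gene clusters, 38 were higher, with a mean of 0.05, and Pcdhga5 (0.25) and Pcdhgc5 (0.20) led them. For these 3 lists camera's adjusted p was 0.0013, 0.011 and 0.0060, and the adjusted p = 0.475, 0.480 and 0.576 with an estimated correlation. Without wild type replicate 3 the means of channels and protocadherins turned to −0.0011 and −0.0056, and without Top2b-low replicate 2 the 3 means were 0.04, 0.0064 and −0.02. Without Top2b-low replicate 3 the channel and protocadherin means were 0.08 and 0.14, and without wild type replicate 2 they were 0.08 and 0.09. Without wild type replicate 1 the channel list was no longer called at a mean of 0.04. Channels and protocadherins stood at −0.11 and −0.22 in N22 minus the other libraries. That difference enters the means without either replicate 3.

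Oligodendrocyte, oligodendrocyte precursor and astrocyte lists were lower on balance. Of 22 oligodendrocyte and myelin genes 21 were lower, with a mean of −0.10 and list means of 0.05 ± 0.09 and −0.05 ± 0.11 (SD, n = 3 each). Myelin basic protein (Mbp) averaged 52778 ± 1699.5 and 48483 ± 2563, Hapln2 and Mag had log2 fold changes of −0.23 and −0.14, and the exception was Opalin (0.24). Of 16 oligodendrocyte precursor markers 11 were lower (mean −0.09), led by C1ql1 (−0.45) and Gpr17 (−0.19), while Tnr was higher (0.14). Of 20 astrocyte markers 16 were lower (mean −0.07), with Gjb6, a connexin, at −0.29 and Itih3 at −0.52. In the same order, camera's adjusted p was 0.00050, 0.026 and 0.032, and the adjusted p = 0.480, 0.475 and 0.590 with an estimated correlation. Each call ended without Top2b-low replicate 3, with means of −0.05, −0.06 and 0.06. That omission leaves N22 in wild type only, so the N22 difference enters these means. For astrocyte markers N22 minus the other libraries was −0.33, and the genotype mean in the N22 pair was −0.12. The astrocyte list was also not called without wild type replicate 1 or 2 (−0.0093 and −0.03), the precursor list without wild type replicate 2 or 3 (−0.08 and −0.10), and the myelin mean was −0.07 and −0.16 without wild type replicates 1 and 3. Without wild type replicate 3 and Top2b-low replicates 1 and 2 the astrocyte mean was −0.16, −0.13 and −0.12. In the 4 libraries outside N22 neither the astrocyte nor the precursor list was called, with means of −0.04 and −0.08 (adjusted p = 0.312 and 0.413), and neither was with array weights (adjusted p = 0.127 and 0.247). With DESeq2 the precursor list was also not called under the replicate block or the N22 term (camera adjusted p = 0.068 and 0.054).

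Transcripts that come from blood and the pituitary varied between single libraries. Of 11 erythrocyte genes 10 were higher in Top2b-low mice, with a mean of 0.88. The haemoglobin gene Hba-a2 counted 3249, 3581 and 1179 in wild type and 39393, 10859 and 1436 in Top2b-low mice, and Alas2 99.6, 108 and 29.9 against 1857, 454 and 44.4. All 8 pituitary hormone genes were lower, with a mean of −1.23, but Gh (growth hormone), chosen after its values were seen, counted 68.0, 0 and 14652 in wild type and 1314, 0 and 21.3 in Top2b-low mice. Pomc counted 69.2, 52.6 and 390 against 139, 12.1 and 23.1. The camera adjusted p was 4.62e-05 and 0.00086, and the adjusted p = 0.475 and 0.480 with an estimated correlation. The erythrocyte mean was 0.41 without Top2b-low replicate 1 and 1.49 without Top2b-low replicate 3, and it was 1.41 with edgeR and with DESeq2. In the 4 libraries outside N22 it was 1.23 and in the N22 pair 0.19. The pituitary mean turned to 0.56 without wild type replicate 3 and to 0.87 in the 4 libraries outside N22, was −2.01, −2.23 and −2.38 without wild type replicates 1 and 2 and Top2b-low replicate 1, and was −0.38 and not called without Top2b-low replicate 2. With edgeR and DESeq2 the pituitary mean was −2.76 and −2.61, and with array weights it turned to 0.996 and was not called.

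Genes of the ribosome and the respiratory chain varied between single libraries, with Top2b-low replicates 2 and 3 on opposite sides. Of 80 cytoplasmic ribosomal protein genes 71 were lower, with a mean of −0.06, and of 44 nuclear-encoded respiratory chain genes 38 were lower, with the same mean to 2 decimals. Rps6 counted 4344, 4275 and 4530 in wild type and 3997, 3587 and 4435 in Top2b-low mice, and Cox7a2 1790, 1565 and 1687 against 1537, 1097 and 1900. Of 15 mitochondrially encoded genes 13 were higher, with a mean of 0.17, led by mt-Co2 (0.55). Camera's adjusted p for the 3 lists was 0.00086, 0.022 and 0.016, and the adjusted p = 0.816, 0.816 and 0.480 with an estimated correlation. Without Top2b-low replicate 2 the first 2 means turned to 0.10 and 0.13, and without wild type replicate 3 to 0.03 and 0.04. Without Top2b-low replicate 3 they were −0.25 and −0.27, without wild type replicate 2 −0.13 and −0.14, and without Top2b-low replicate 1, where neither was called, −0.04 and −0.04. With the start of the library name as a term the mitochondrial mean was 0.31 and the list was called. It was not called without wild type replicate 3 or Top2b-low replicate 3 (0.05 each) and was 0.26 and 0.29 without wild type replicate 1 and Top2b-low replicate 2. Its mean turned to −0.07 in the 4 libraries outside N22. There the ribosomal and nuclear respiratory means were −0.16 and −0.17, against 0.12 and 0.16 in the N22 pair. For these lists N22 minus the other libraries was 0.42 and 0.46, which enters the means without either replicate 3. With edgeR and DESeq2 the ribosomal mean was −0.03 in both, and the nuclear respiratory mean was −0.01 and −0.02 and not called (adjusted p = 0.191 and 0.141).

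Interferon and inflammation genes were higher on balance, 20 of 30, with a mean of 0.13. The interferon-induced genes Rsad2 (log2 fold change 1.06), Ifit3 (0.56), Ifit1 (0.68) and Oasl2 (0.51) led them. Of 17 ependymal markers 13 were lower (mean −0.14), with Pifo at −0.63 and Hdc at −0.56, and of 26 GABAergic neuron markers 17 were lower (mean −0.07), with Nxph1 at −0.20 and the glutamate decarboxylase Gad2 at −0.19. By camera the adjusted p was 0.012, 0.038 and 0.047, and the adjusted p = 0.480, 0.576 and 0.475 with an estimated correlation. With the replicate block in limma the ependymal and GABAergic lists were no longer called (adjusted p = 0.085 and 0.075). With edgeR the interferon list was not called under that block or the N22 term (camera adjusted p = 0.069 and 0.057). In the 4 libraries outside N22 their means were −0.0030 and −0.03 and neither was called (adjusted p = 0.878 and 0.369), against −0.42 and −0.14 in the N22 pair. The interferon list was not called without wild type replicate 3 (0.04) or Top2b-low replicate 2 (0.07) and was 0.23 without Top2b-low replicate 3 and 0.21 with no filter. The ependymal list was not called without wild type replicates 1 and 3 (−0.12 and −0.05) or Top2b-low replicates 2 and 3 (−0.11 and −0.09) and was −0.25 and −0.23 without wild type replicate 2 and Top2b-low replicate 1, and the GABAergic list was called only without wild type replicate 1 among the 6 omissions, with means from −0.10 to −0.04.

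**Figure D4:**
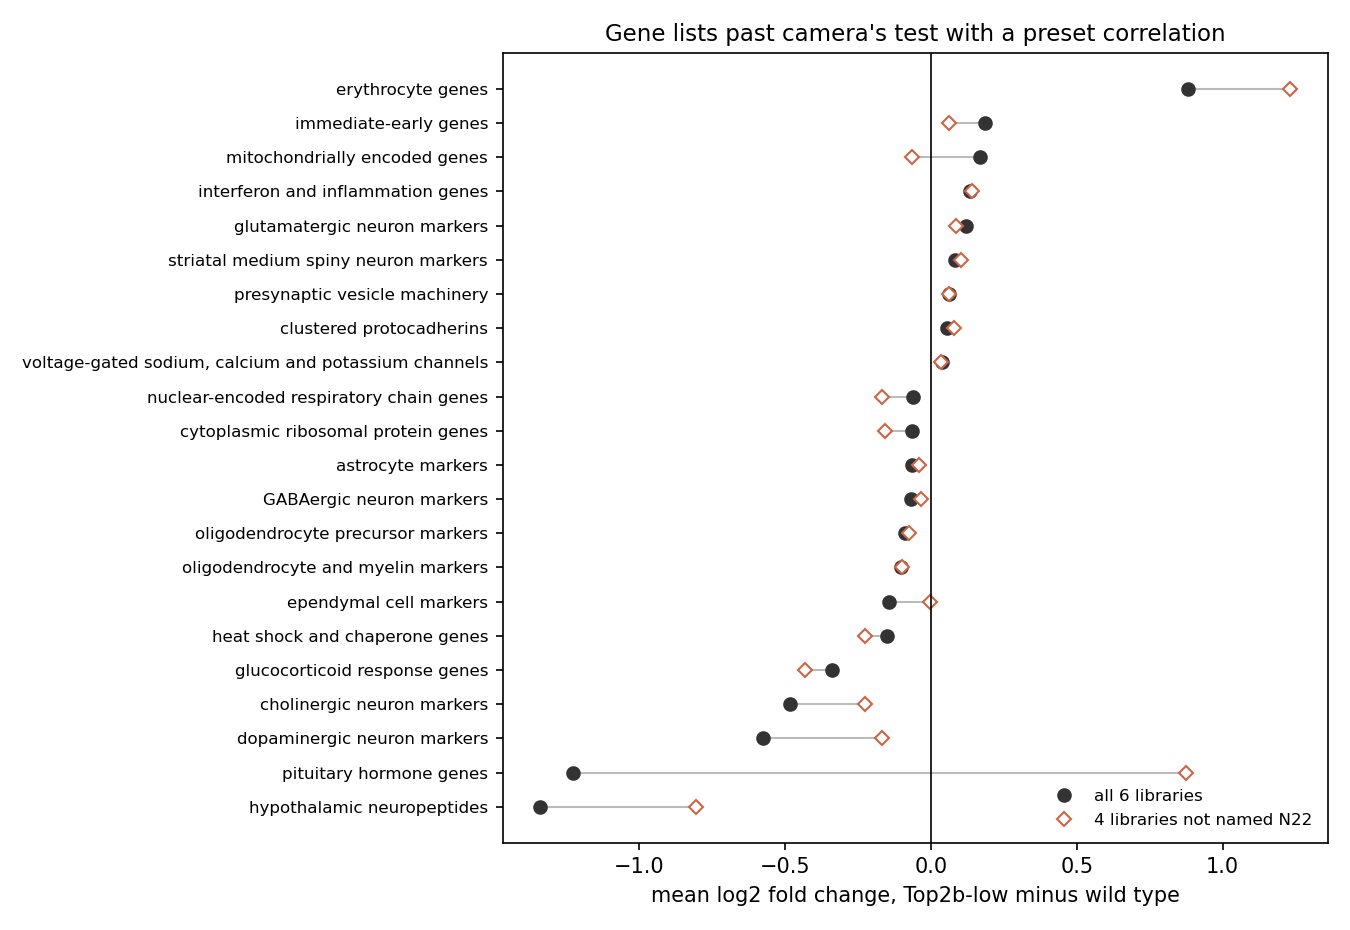
Mean log2 fold change, Top2b-low minus wild type, of the 22 gene lists called by camera with a preset correlation, in all 6 libraries (filled circles) and in the 4 libraries whose names do not begin with N22 (open diamonds). Hypothalamic neuropeptides lie at −1.34 and −0.81 and pituitary hormone genes at −1.23 and 0.87.

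The other 19 lists were not called in all 6 libraries, with camera adjusted p from 0.164 to 0.994. In the 4 libraries outside N22 glutamate receptors (0.06, adjusted p = 0.017) and choroid plexus markers (−0.09, adjusted p = 0.035) were called, and in the N22 pair their means were −0.03 and 0.02. With DESeq2 in those 4 libraries GABA and glycine receptors were also called lower (−0.09, camera adjusted p = 0.040). Choroid plexus markers were also called lower with array weights and without wild type replicate 3 or Top2b-low replicate 2. Cerebellar markers were called lower without wild type replicate 3 or Top2b-low replicate 2 and higher without wild type replicate 1 or Top2b-low replicate 3. The omission of single replicates also brought calls for meningeal, hippocampal, olfactory bulb, histone, serotonergic and noradrenergic, and synaptic adhesion lists. The meningeal list was called lower without Top2b-low replicate 1 or 2 and higher without Top2b-low replicate 3. With the start of the library name as a term the cerebellar, choroid plexus and histone lists were called. Long neuronal genes went both ways, 27 higher and 22 lower of 49, with the potassium channel gene Kcnq5 at 0.23 and the adhesion gene Csmd3 at −0.14. Their mean was −0.01, their median 0.01 and the camera direction higher, and signs also differed among mean, median and camera for circadian clock genes and among mean and median for p53 and DNA damage response genes. The 18 topoisomerases and their repair partners were not called either, and apart from Top2b their smallest unadjusted p belonged to Rad50 (log2 fold change 0.20) and Top3b (0.16). The 13 neighbours of Top2b on chromosome 14 had a mean of −0.06, with Nek10 at −0.39 and Thrb at −0.02. Neurotransmitter receptors (glutamate, GABA and glycine), synaptic adhesion and axon guidance genes, thalamic, cerebellar, hippocampal, olfactory bulb, serotonergic and noradrenergic neuron markers, microglia, endothelial and mural cells, choroid plexus, meningeal fibroblasts, replication-dependent histones and sterol synthesis genes made up the rest. Among microglial markers P2ry12 stood at 0.23 and Tmem119 at −0.15.

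Genes spanning more than 100 kb, a class that topoisomerases act on in neurons, were slightly higher relative to shorter genes in the Top2b-low library of each same-numbered pair. This did not hold with replicates 1 and 2 matched the other way. Per library, the mean log2 level of the 2377 long genes minus that of the 14138 others was 1.082 ± 0.067 in wild type and 1.101 ± 0.071 in Top2b-low mice (SD, n = 3 each), a difference of 0.02, less than the spread between replicates. The two-sided exact permutation test without pairs gave p = 0.7. Within pairs, which rest on the values alone, the differences were 0.0179, 0.0234 and 0.0151 (mean 0.0188 ± 0.0042, SD, n = 3), and the exact sign-flip test gave p = 0.25, the smallest that 3 pairs allow. In the other matching, wild type replicate 2 (1.142) stood above Top2b-low replicate 1 (1.112). The constant sign and the small SD within pairs thus depend on the numbering. Camera gave p = 0.036 with the preset and p = 0.507 with an estimated correlation, and with the replicate block p = 0.020 and p = 0.022, the values within pairs and the block with an estimated correlation having been computed after the data were examined. Across genes, which are not independent replicates, the Spearman correlation of fold change with span was 0.05. Leaving out wild type replicate 3 or Top2b-low replicate 2 turned the difference to −0.02 and −0.01, and leaving out wild type replicate 2 or Top2b-low replicate 3 moved it to 0.05 and 0.06, each omission leaving a library without its pair. With no filter the difference was −0.00043, and with the start of the library name as a term 0.0029 and not called.

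Small p values were counted on chromosome 14, where Top2b lies, against the other chromosomes. No gene passed the adjusted threshold of limma on any chromosome. At an unadjusted p under 0.01 chromosome 14 held 1 of 584 tested genes, Top2b, against 21 of 15931 elsewhere (Fisher's exact test, two-sided, p = 0.547). The smallest p of the 20 chromosomes was that of chromosome 12, with 3 of 615 genes (Fisher's exact p = 0.0468, adjusted p = 0.754).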

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

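The N22 term, the 4 libraries outside N22, the N22 pair, the replicate block with DESeq2, with edgeR or with an estimated correlation, and the length difference within pairs or with an estimated correlation were chosen only after the data were seen, and the other alternatives before. The count of genes was 0 under all planned settings except the omission of single replicates, which gave 0 to 1 (Avp without Top2b-low replicate 1), and it was 21 with DESeq2 and the N22 term, 14 with DESeq2 and the replicate block, and 5 with DESeq2 on the 4 libraries outside N22. Limma with the replicate block called 0 genes (1169 at an unadjusted p under 0.05) and edgeR with it 0 (1168). The Top2b difference kept its direction under every setting and passed the threshold in those 3 DESeq2 fits, at −0.423, −0.424 and −0.463. In each of them 1 call lay on chromosome 14, as did 1 gene at an unadjusted p under 0.01. Fixed lists numbered 22, and 0 with an estimated correlation, 0 with fry and 0 with the replicate block and an estimated correlation, and 13 to 22 with single replicates left out. Under the block at the preset correlation 20 lists were called, with the ependymal and GABAergic lists lost, and pairing changed no other limma call except that of the length difference with an estimated correlation. The length difference (0.0188) was −0.00043 with no filter, and no longer past the threshold with an estimated correlation (0.0188, but past it with the replicate block too), without limma's trend (0.0188), with array weights (0.0188), with the start of the library name as a term (0.00287), with spans over 50 kb (0.0157) and in the 4 libraries outside N22 (0.0206), and ran from −0.0172 to 0.0566 with single replicates left out. Pituitary genes turned to 0.996 with array weights, 1.06 with DESeq2 and the N22 term, and 0.875 and 2.23 in the 4 libraries outside N22 with limma and DESeq2. In those 4 libraries the mitochondrial list turned to −0.0651 and −0.0406. With the start of the library name as a term the nuclear respiratory list turned to 0.0700, past the threshold, and the ribosomal list to 0.0413. Omitting single replicates moved immediate-early genes from −0.0673 to 0.390, channels from −0.00111 to 0.0798, pituitary genes from −2.38 to 0.563, astrocyte markers from −0.164 to 0.0566, nuclear respiratory genes from −0.268 to 0.130, protocadherins from −0.0190 to 0.138 and ribosomal genes from −0.251 to 0.0981. Each omission leaves fewer samples, and that of either replicate 3 leaves N22 in 1 genotype only. The N22 difference then enters the genotype difference. Immediate-early genes, at −0.572 in N22 minus the other libraries, went to −0.0673 without wild type replicate 3. They went to 0.314 without Top2b-low replicate 3. Their highest value came without wild type replicate 2, so the N22 split does not account for every move. Other causes were not tested. Of the other list values 501 kept direction and side of the threshold and 75 kept direction but were no longer past it, and of the values for single named genes 291 stayed as they were and 6 passed the threshold. Depth limits low genes most, since 3 reads equal up to 3.76 normalised counts in the shallower libraries.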

Other observations

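The tests on Hox genes, on the imprinted genes as a set and on splits for the gene lists were chosen only after the result was seen, as were the omissions of single replicates for the imprinted genes, the settings with an N22 term or the replicate block in DESeq2, and the 4 libraries outside N22. The imprinted genes, the Hox genes and the hypothalamic transcription factors and receptors were lists drawn up after the data had been examined.

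Imprinted genes, expressed from 1 parental allele and many of them abundant in hypothalamus and brainstem, were lower in Top2b-low mice in 38 of 42 tested members. Their mean log2 fold change was −0.32, and the library means were 0.20, 0.15 and 0.14 in wild type and 0.12, −0.15 and −0.46 in Top2b-low replicates 1 to 3. The groups did not overlap, but wild type replicate 3 (0.137) and Top2b-low replicate 1 (0.124) lay close. With 3 against 3 such a separation has a probability of 0.1 by chance, and the list was drawn up after the data were examined. Zim1 fell by 0.85 and Nap1l5 by 0.29 on the log2 scale under DESeq2 with an N22 term or a replicate block, respectively (adjusted p = 0.00854 and 0.0241), and neither passed limma. At an unadjusted p under 0.05 limma left 10 of the 42. Hypothalamic peptide genes outside the 4 described, chosen after their values were seen, were also low in Top2b-low replicates 2 and 3. Oxt counted 197, 191 and 340 in wild type and 181, 9.71 and 2.96 in Top2b-low replicates 1 to 3, and Hcrt 124, 154 and 159 against 96.0, 9.71 and 0.59.

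The libraries named N22 stood apart from the other 4 in both genotypes. Thinning them to the mean depth of the other 4 left the cerebellar list −3.60 log2 units lower, against −3.58 as deposited. Thinning takes reads from all genes alike, so it could not restore transcripts near 0 and does not decide on depth. Greater depth adds reads, yet the deeper N22 libraries held 2 and 6 reads of Hox genes, against 85 to 292 in the other 4. That argues against depth. GC content was argued against, since a correction left −3.56. Less cerebellum and hindbrain in the tissue may account for it. Hox genes, expressed in hindbrain and spinal cord, summed to 1.42 and 3.55 normalised counts in the N22 libraries (2 and 6 reads). In replicates 1 and 2 they summed to 223 and 366 in wild type and to 118 and 103 in Top2b-low mice. Hindbrain content may thus also differ between genotypes outside N22, which bears on Slc6a5 and was not tested. For the N22 split a biological difference between the mice stays open as untested, and genotype cannot be its source, since each genotype held 1 N22 library.

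Lower hypothalamic neuropeptides in Top2b-low mice may follow the amount of hypothalamus in the sample. The summed count of 15 other hypothalamic genes was 899, 927 and 937 in wild type and 799, 365 and 210.0 in Top2b-low replicates 1 to 3, with the most abundant, Gpr101, at 334, 359.7 and 373 against 337, 153 and 102 and Irs4 at 272, 276 and 286 against 215, 72.8 and 17.7. With that sum as a covariate the genotype difference of the neuropeptide list went from −1.34 to −0.16 (SE 0.46). The deviations of the sum and the list within genotypes gave r = 0.896 (n = 6, exact permutation within genotypes p = 0.0556, adjusted over 2 relations 0.111). They gave rho = 0.943 (permutation p = 0.111, adjusted 0.222). Neither passed, with 0.0278 the smallest p that 36 arrangements allow, and r was 0.777 without the 2 farthest samples. The N22 libraries are too few for a value of their own. A genotype effect on hypothalamic neurons as a whole would lower both measures too and stays open.

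The imprinted genes may move for the same reason. With the covariate their difference went from −0.32 to 0.0388 (SE 0.0522), and the deviations within genotypes gave r = 0.983 (permutation p = 0.333, adjusted over 2 relations 0.333), rho = 0.486 (permutation p = 0.583, adjusted 0.583) and r = −0.563 without the 2 farthest samples, so that the relation did not pass and rests on those samples. Against the other genes the imprinted set was lower with an estimated correlation (camera p = 0.0414, and 4.05e-15 with the preset one), a test run on a list chosen after its genes were seen. With single replicates left out the estimated p was 0.00504 without Top2b-low replicate 1 and 0.0789 to 0.136 in the other 5 omissions, and the difference was −0.18 without Top2b-low replicate 3. A direct effect of the allele on imprinted genes stays open beside differences in dissection.

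The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. For limma's count of genes, 0, all 10 splits gave as many and the highest other gave 4, a split that set wild type replicates 1 and 2 and Top2b-low replicate 2 against the rest and so placed both N22 libraries on 1 side. For lists called with the preset correlation only the real split, 1 of 10, gave 22, and the highest other gave 18. Among the other splits that part all 3 same-numbered pairs the lists numbered 14, 10 and 15. Splits that placed both N22 libraries together had 1755 to 3164 genes at an unadjusted p under 0.05, against 262 for the real split, which points to the N22 difference as the main structure of the samples.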
